A study of Homo sapiens with 6 samples.

How the data were processed

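RNA of J82 cells, an established human bladder cancer cell line, was measured on 6 one-colour (Cy3) Agilent gene expression arrays. Per the labels, cells had been transfected with an siRNA against ANLN (siANLN) or with a control siRNA (siNC), and total RNA was taken after 24, 48 or 72 h, with 1 array for each siRNA at each time point. The labels do not say how many siRNAs were used, nor that the 3 arrays of a group came from separate cultures. The main fit takes out differences between time points. Its p-values therefore measure how the siANLN to siNC difference varied over the 3 time points. They need not reflect a spread between separate cultures, and part of the variation may be technical.

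Per the file headers and the submitters' processing notes, the arrays were scanned and read with Agilent Feature Extraction 11.0.1.1, and the header names genome build hg19. The processed spot intensity in the deposited files is on a linear scale, with background subtraction and detrending within each array and no scaling between arrays, per the file headers. The authors' value table, 1 column per array on a log2 scale, is also deposited, with its processing unstated. The lowest correlation of a column with log2 of the same array's processed signal was 0.996. The columns had the same median of 7.74 in all 6 arrays, and lay within 0.1 of quantile-normalized processed signals, after centring both on their medians, for 92.9% of values. Its direction and log base are thereby settled, while the constant that sets its centre is not; the table served as an alternative source of values.

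Each array held 44495 spots, of which 43118 were probe spots outside the controls. Between 254 and 337 probe spots per array carried an outlier flag and were left out where another spot of the probe remained, and 0 were saturated. Log2 of the processed signal, minus the array's 75th percentile, was averaged over the spots of a probe, giving 34127 probes. The files hold no gene names, so each probe's transcript accession was matched, without version, to the RefSeq gene table of assembly GRCh38.p14, which gave symbols to 25771 probes (19740 symbols); the other 8356 probes kept the name in the file. That table's coordinates belong to another build than the files and are not used here. A probe was kept if it was well above background on all 3 arrays of at least 1 siRNA group, which left 23780 probes, and each gene was represented by its probe with the highest mean over the 6 arrays. The 19361 genes tested comprised 14980 with a symbol and 4381 without. Of the 1001 genes called below that had several passing probes, 738 had all probes on the same side. Where all 3 arrays of one group were not well above background, the ratio is given as at least N-fold, from the mean of the brighter group against, per array, the higher of the probe's own signal and the lowest normalized signal of any probe well above background on that array.

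limma 3.58.1 in R 4.3.3 was fitted to all 6 arrays with time point as a factor and the siRNA as the term of interest (lmFit, eBayes, 2 residual degrees of freedom plus a prior of 1.78). The same fit gave the contrast of 72 h with 24 h. A linear change of the siRNA effect with time was fitted as an added term, with 1 residual degree of freedom plus a prior of 2.23. P-values are two-sided and were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, against the genes outside the list, and again with an estimated correlation. With an estimated correlation camera uses only the few residual degrees of freedom of the fit. A list can therefore lose its call there without strong correlation between its genes. fry, added after the data were seen, tested whether a list's genes moved, on balance, one way. The 16 lists hold 511 genes, of which 504 were on the array and 469 were tested. The lists, the limma and camera tests and the alternatives were fixed before the data were examined, apart from what is said to have been added later. Where a number of genes is given per list, it is the number at adjusted p < 0.05 over all genes tested, and the number "adjusted over the list alone" stands beside it.

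Genes are named by a rule fixed beforehand. It takes ANLN, then the 12 higher and 12 lower genes of largest log2 change among those past the threshold with the same sign at all 3 time points and a regular gene symbol, and for each list up to 4 members with the largest moderated statistic. For the time contrast and the slope it takes 6 per direction, filled by the smallest unadjusted p where none pass, among genes at least 2-fold apart between 72 h and 24 h, which for the slope means over those 48 h. One gene of the Y chromosome met the rule and is not named, and some other genes that met it are not reported here. A gene outside this rule is said to have been chosen after its values were seen.

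The fits were tested on simulated arrays drawn from the means and fitted spread of all 19361 genes. With 200 genes changed, the siRNA comparison recovered 34.3% of changes of 0.5 on the log2 scale, 92.5% of changes of 1 and 98.5% of changes of 2, with 10 false calls among 160. For 72 h against 24 h the shares were 4.48%, 73.1% and 89.4%. For the slope they were 0% at 0.5 per 24 h, 16.4% at 1 and 89.4% at 2. With 4758 genes changed, 1586 at each of the sizes 0.5, 1 and 2, the siRNA comparison recovered 90.3% at a size of 0.5. The genes called in the data had a median absolute log2 change of 0.39. The simulated changes were thus larger, and this share need not hold for the data. A simulated shift of -0.25 in the 47 tested genes of the G2/M and mitosis list was found in 50 of 50 draws, with 1 false list call over all draws. The simulated genes were drawn independently, without correlation between genes or differences between scans. The rates of false calls therefore need not hold for the real arrays.

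The time point pairs each siANLN array with an siNC array. The deviations of the paired arrays from their group means correlated across genes at 0.20 for 24 h, 0.02 for 48 h and 0.02 for 72 h. By scan time in the file headers, the arrays fell into 3 scans. The siANLN arrays of 24 h and 48 h formed scan 1, the siANLN array of 72 h was scan 2, and the 3 siNC arrays were scan 3. No scan holds both groups, so a fit with the scan as a fixed term or within a scan cannot be made, and the scan was fitted as a random block without the time term. The alternatives were quantile normalization, centring on the median of detected probes, normexp background correction with an offset of 50 followed by quantile normalization, the authors' table, no filter on dim probes, a filter on all 6 arrays, other ways to treat several probes of a gene, a fit without the time point, an intensity trend with a robust prior, and leaving out each array. The files have no mean signal column, so normexp used the spot and local background medians. A restriction to brighter genes, those with a mean signal above the median of all genes tested, was added after the data were seen. The number of arrays limits the precision of every value. The siRNA sequence and probe positions were not used here.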

Results

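The study asked how gene expression in J82 bladder cancer cells changes when ANLN is silenced. ANLN encodes anillin, an actin-binding scaffold of the contractile ring that pinches dividing cells apart. There were 3 siANLN and 3 siNC arrays, 1 of each at 24, 48 and 72 h after transfection. The 75th percentile of the processed signal was 1817, 2524 and 2420 on the siANLN arrays at 24, 48 and 72 h, and 1996, 2036 and 1610 on the siNC arrays. Detection differed between arrays. In the siANLN group 91.4%, 87.2% and 70.7% of probe spots were well above background at 24, 48 and 72 h, against 73.9%, 73.5% and 71.4% in the siNC group. The siANLN arrays of 24 h and 48 h, which were scanned together, thus detected more probes than the other 4.

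ANLN itself was lower in siANLN at every time point. Its normalized log2 signal was 0.23 ± 0.12 (SD, n = 3) in siANLN and 2.20 ± 0.09 (SD, n = 3) in siNC, a difference of -1.98 ± 0.07 (SE, limma adjusted p = 0.0165), or 3.93-fold. The log2 ratio was -2.12 at 24 h, -1.98 at 48 h and -1.83 at 72 h, so the targeted gene ran with the labels in all 3 pairs. All 6 arrays measured it well above background, with 1 probe. The call was kept without either array of 72 h (adjusted p = 0.0437) and lost without the others. The adjusted p became 0.110 without either array of 24 h and 0.168 without either array of 48 h, while the log2 change stayed between -2.05 and -1.90 whichever array was left out. Without the filter on dim probes the adjusted p was 0.101, and over all alternatives it ran from 2.5e-04 to 0.168.

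Beyond ANLN, 11 genes that rose in siANLN are named by the rule. IL24, a cytokine of the interleukin-10 family, rose by 2.07 ± 0.07 on the log2 scale (SE, adjusted p = 0.0165), and IL11, a cytokine of the interleukin-6 family, by 1.58 ± 0.08. AMTN, which encodes the enamel protein amelotin, rose by 1.85 ± 0.07, and the ARF-like GTPase gene ARL14 by 1.74 ± 0.10. ARHGEF25, which encodes a guanine nucleotide exchange factor, rose by 1.91 ± 0.18, and RELN, which encodes the extracellular glycoprotein reelin, by 2.01 ± 0.11, although RELN was well above background on only 1 of 3 siNC arrays. The chemokine gene CCL3L3 rose by 1.64 ± 0.04; its near-identical copies may share the probe's signal. For the remaining named genes the siNC arrays were not well above background, so only a bound, on the scale of the processed signal, can be given. The long noncoding RNA LINC00473 was at least 3.35-fold higher in siANLN, the phospholipase gene PLA2G4D at least 3.10-fold, the matricellular thrombospondin gene THBS2 at least 2.95-fold and the stromelysin gene MMP3 at least 2.12-fold. The sizes for dim genes depended on the background correction. With normexp and its offset, which is added to every signal and so draws dim signals together, the log2 change was 0.80 for RELN, 1.104 for ARHGEF25 and 0.81 for ARL14. On that scale the differences of LINC00473, PLA2G4D, THBS2 and MMP3 were between 0.44 and 0.86, below the bounds above, which therefore do not hold across background corrections. All 7 were still past the threshold.

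Among the genes that fell, SIAE, the gene of sialic acid acetylesterase, had a log2 change of -2.71 ± 0.05 (SE, adjusted p = 0.0165) and the histidine triad gene HINT3 of -2.07 ± 0.06. The noncoding RNA LINC00467 fell by 1.85 on the log2 scale, and NRN1, which encodes neuritin, by 1.68. PMP22, a membrane protein of myelin, fell by 1.54, the inflammatory cytokine gene IL1B by 1.52, and UGDH, whose enzyme makes UDP-glucuronate, by 1.51. PLEKHS1 fell by 1.41, with its 3 probes not all on the same side. With the mean of a gene's probes, the log2 change was -0.79 for PLEKHS1 and -1.22 for LINC00467. A further 4 genes are best known from blood cells. They are PLEK (pleckstrin), ITGB2 (the β2 integrin), ELANE (neutrophil elastase) and CTSG (cathepsin G), with fitted log2 changes of -3.37 ± 0.55, -1.83 ± 0.13, -1.63 ± 0.17 and -1.61 ± 0.32. The size for PLEK is uncertain, since only 1 of 3 siANLN arrays measured it well above background. ELANE was well above background on 2 of 3, and normexp gave -1.23 for PLEK, -0.95 for ITGB2, -1.08 for NRN1 and -0.91 for ELANE. The PLEK call was lost whichever array was left out, with an adjusted p of 0.0676 without either array of 72 h. In the fixed list of blood cell markers 3 of 15 tested members rose and 2 fell (camera adjusted p = 0.547). The myeloid receptor gene CSF1R and the leukocyte lysosome gene LAPTM5 fell by 0.49 and 0.59, as these 4 genes did, while the T cell genes CD8A and CD3E and the pan-leukocyte gene PTPRC rose by 0.41, 0.47 and 0.47. CD3E was named after its value was seen.

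**Figure D1:**
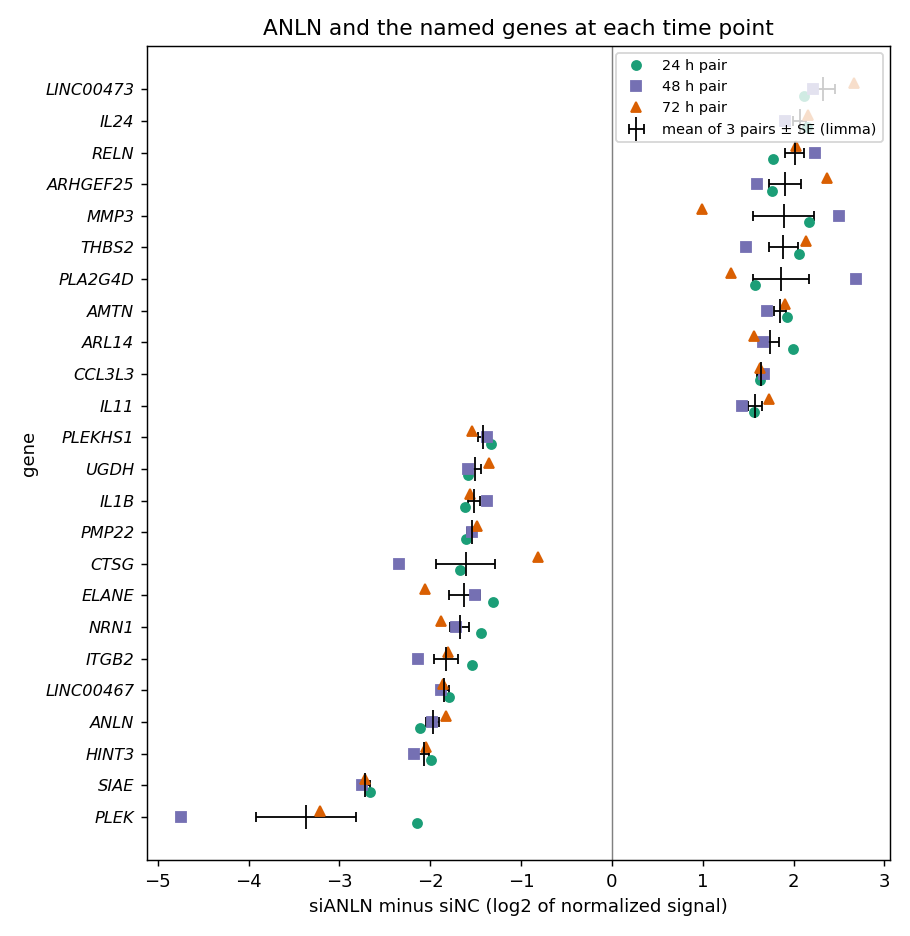
Log2 difference of siANLN and siNC for ANLN and the genes named by the fixed rule, with the 3 pairs as coloured points (24, 48 and 72 h) and the limma mean ± SE over the 3 pairs as black bars. All 3 points of each gene lie on one side of 0; ANLN lies between -2.12 and -1.83, and the points of PLEK, MMP3, PLA2G4D and CTSG are the most spread.

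In all, 4758 of 19361 genes (24.6%) differed between siANLN and siNC at adjusted p < 0.05, of which 2609 were higher and 2149 lower in siANLN. Most differences were small. The median absolute log2 change of the called genes was 0.39, and 101 of the higher and 63 of the lower genes were at least 2-fold apart. All 4758 had the same sign in the 3 pairs, which adds little, since a call needs the pairs to be alike. The share of higher genes depended on the scaling, at 54.8% here, 43.1% with quantile normalization and 35.5% with median centring. No gene passed without either array of 24 h (5976 at unadjusted p < 0.05 in limma), without either array of 48 h (4798) or without the filter on dim probes (7243), and 2679 passed without either array of 72 h.

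Of the 47 tested genes of the G2/M and mitosis list 22 fell and 1 rose (32 and 1 adjusted over the list alone), with a median log2 change of -0.25 and a camera adjusted p of 3.7e-10 at the preset correlation (adjusted p = 0.553 with an estimated correlation). PIMREG, a regulator of the metaphase-to-anaphase transition, fell by 0.99 on the log2 scale, the topoisomerase gene TOP2A by 0.64, CDCA3 by 0.52 and the mitotic kinase gene PBK by 0.51. NCAPH, a condensin subunit and the member that rose, changed by 0.51; it was named after its value was seen. The list's median was -0.26, -0.34 and -0.20 at 24, 48 and 72 h, and it lay below all of 10000 random lists matched on mean signal, a comparison chosen after the data were seen but before its own outcome was known, whose 5th to 95th percentile ran from -0.12 to -0.01.

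In the list of the contractile ring and cytokinesis, which leaves ANLN out, 10 of 35 genes fell and 3 rose (11 and 3 adjusted over the list alone), with a median of -0.11 and a camera adjusted p of 3.2e-04 (adjusted p = 0.553 with an estimated correlation). BIRC5 (survivin) fell by 0.52, the citron kinase gene CIT by 0.55 and the borealin gene CDCA8 by 0.43, all 3 known from the midzone and midbody. CHMP4B, a subunit of the abscission machinery, rose by 0.50. AURKB and INCENP rose as well, by 0.29 and 0.27, and were named after their values were seen. Genes of G1/S and DNA replication fell in 12 of 45 cases and rose in 3 (14 and 4 adjusted over the list alone), with a median of -0.13 and a camera adjusted p of 5.2e-04 (adjusted p = 0.572 with an estimated correlation). TK1, PCNA and MCM6, which serve nucleotide supply and the replication fork, fell by 0.38, 0.41 and 0.36, whereas the phosphatase gene CDC25A rose by 0.52. Both calls were lost with quantile normalization (camera adjusted p of 0.0728 and 0.0647). Over the alternatives the median ran from -0.18 to -0.09 for the contractile ring list and from -0.20 to -0.06 for the G1/S list. Against random lists matched on mean signal, the medians of these lists stood at the 12.1st and the 4.61st percentile.

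Most interferon-stimulated genes of the fixed list rose. Of 39 tested genes 26 rose and 0 fell (30 and 0 adjusted over the list alone), with a median of 0.36 and a camera adjusted p of 8.5e-08 (adjusted p = 0.553 with an estimated correlation). The chemokine gene CXCL10 rose by 1.12 ± 0.06 (SE), the antiviral genes OASL and OAS1 by 0.74 and 0.65, and IFI44L by 0.64. The list's median was 0.38 at 24 h, 0.34 at 48 h and 0.31 at 72 h. Of 29 genes of NF-kB signalling and inflammatory cytokines 17 rose and 3 fell (18 and 5 adjusted over the list alone), with a median of 0.34 and a camera adjusted p of 0.0357 (adjusted p = 0.572 with an estimated correlation). Its leading members were IL24 and IL11, given above, CXCL3, which rose by 0.57, and IL1B, which went the other way. Its signalling members were mixed. NFKBIZ rose by 0.46 and BIRC3 fell by 0.44, while NFKBIA (-0.14), TNFAIP3 (0.03), RELB (-0.06) and NFKB1 (-0.09) did not pass. These signalling genes were named after their values were seen. The camera call of this NF-kB list was lost with the mean of a gene's probes (adjusted p = 0.0615) and without either array of 72 h (adjusted p = 0.0802). With the arrays split in other ways than by siRNA, 3 of the other 9 splits also put 5 lists past the threshold at the preset correlation.

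In fry's test of a shift in one direction, the contractile ring list (adjusted p = 0.0113) and the G2/M, interferon and NF-kB lists (each adjusted p = 0.0146) passed, and G1/S did not (adjusted p = 0.0531). The other 11 lists did not pass with camera, and of these the lysosome and autophagy list passed with fry (adjusted p = 0.0113). fry sets a list against no change and not against other genes. With the scaling used, the median log2 change of the brighter genes (mean signal above the median of all genes tested) was -0.055. In the contractile ring list 33 of 35 genes are among these, so fry cannot separate its shift from that general lean. In the actin cytoskeleton, SRF and YAP list 7 of 32 genes fell and 4 rose (7 and 5 adjusted over the list alone), with a camera adjusted p of 0.143. The list passed without the filter on dim probes (adjusted p = 0.0471) and without either array of 48 h (adjusted p = 0.0480), and its adjusted p was 0.801 with quantile normalization. TEAD1, the partner of YAP, fell by 0.64, CNN2 by 0.54, CALD1 by 0.48 and TPM2 by 0.37. In the lysosome and autophagy list 9 of 26 rose and 2 fell (13 and 3 adjusted over the list alone), at a camera adjusted p of 0.197. The autophagy receptor gene SQSTM1 rose by 0.40, while the cathepsin gene CTSB fell by 0.83. With quantile normalization this list passed at the preset correlation (camera adjusted p = 7.6e-04), as did the sterol list (0.0340) and the unfolded protein list (0.0114). With an estimated correlation, and scaling on the 75th percentile, the camera adjusted p of these lists was 0.572, 0.732 and 0.816. Among 21 epithelial and urothelial genes 3 rose and 7 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.463). The basal keratin gene KRT14 rose by 1.09 and the claudin gene CLDN1 by 0.60, and CLDN4 and the luminal factor gene FOXA1 fell by 0.65 and 0.46. Of 35 mesenchymal and matrix genes 8 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.671), among them S100A4, which fell by 0.77, and COL3A1 and SNAI2, which rose by 0.65 and 0.47.

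Of 24 p53 target genes 5 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.547). The polymerase gene POLH fell by 0.66 and TIGAR by 0.63. Of 29 MAP kinase and AP-1 genes 7 rose and 5 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.463); FOSB rose by 0.51 and DUSP2 by 0.55. In the unfolded protein and integrated stress list 5 of 32 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.668), with DDIT3 higher by 0.35 and ATF4 at -0.33. Of 30 hypoxia and glycolysis genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.668), and of 22 sterol genes 3 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.547). Of the 8 endothelial and neural markers tested 1 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.668), and of the 15 blood cell markers 3 rose and 2 fell with either adjustment. The median, mean and camera direction did not all share a sign for the epithelial list (0.02, -0.01 and down), the hypoxia list (0.01, 0.04 and down), the mesenchymal list (-0.01, 0.06 and down) and the p53 list (0.06, -0.06 and down).

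**Figure D2:**
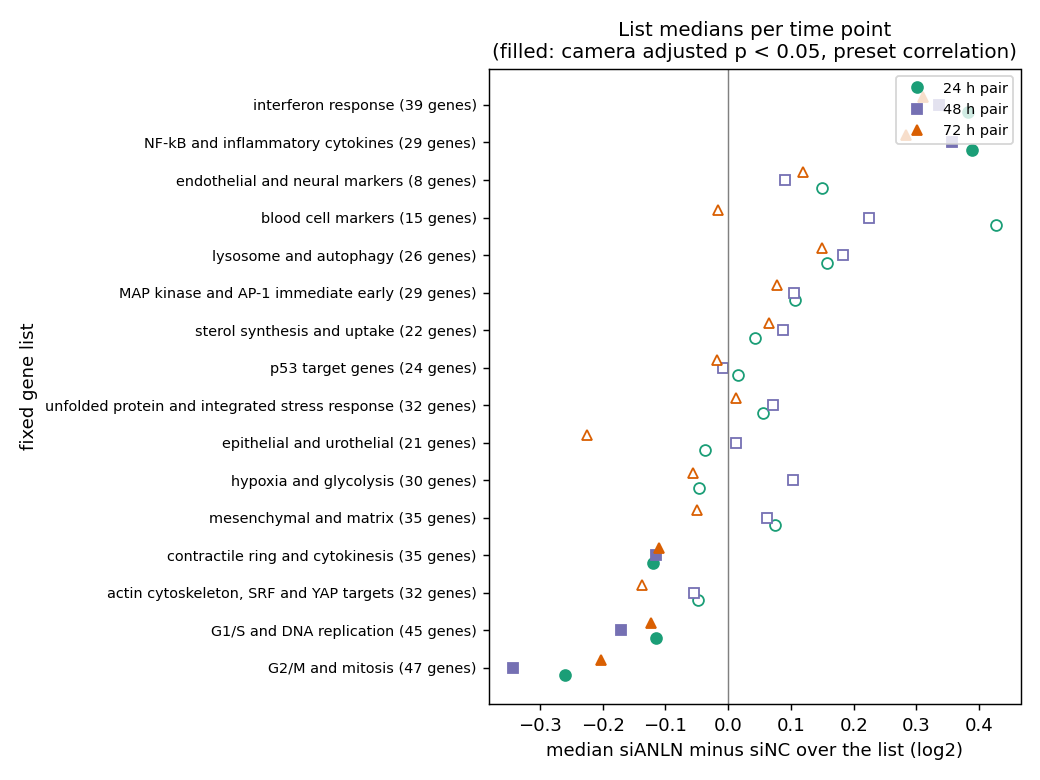
Median log2 difference of siANLN and siNC over the tested genes of each fixed list (y axis, with the number of genes), 1 point per pair at 24, 48 and 72 h; filled points mark lists with a camera adjusted p < 0.05 at the preset correlation. The interferon list lies between 0.31 and 0.38 and the G2/M and mitosis list between -0.34 and -0.20.

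Within single time points, without replicates, 647 genes were at least 2-fold higher and 102 at least 2-fold lower in siANLN at 24 h. The numbers were 358 and 89 at 48 h, and 179 and 147 at 72 h. Among the brighter genes, those with a mean signal above the median of all genes tested, the higher and lower numbers were 34 and 60 at 24 h, 28 and 35 at 48 h, and 35 and 33 at 72 h. With quantile normalization the balance at 24 h turned, with 235 higher and 263 lower, and the numbers were 172 and 129 at 48 h, and 158 and 120 at 72 h. In one direction at all 3 time points 93 genes were at least 2-fold apart, 52 higher and 41 lower. If the time points were independent, 0.111 and 0.00356 would occur. The pairs share probes and scans, so a bias of either can recur in all 3, and the excess cannot be credited to the siRNA alone. Of the 93 genes, 91 were among the called genes. With normexp and quantile normalization the number was 32, with 9 higher and 23 lower, among the brighter genes it was 33, with 11 higher and 22 lower, and without either array of 72 h, over the 2 remaining time points, it was 229. Log2 ratios correlated across genes at 0.71 between 24 h and 48 h, 0.46 between 24 h and 72 h and 0.51 between 48 h and 72 h; genes are not independent replicates.

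**Figure D3:**
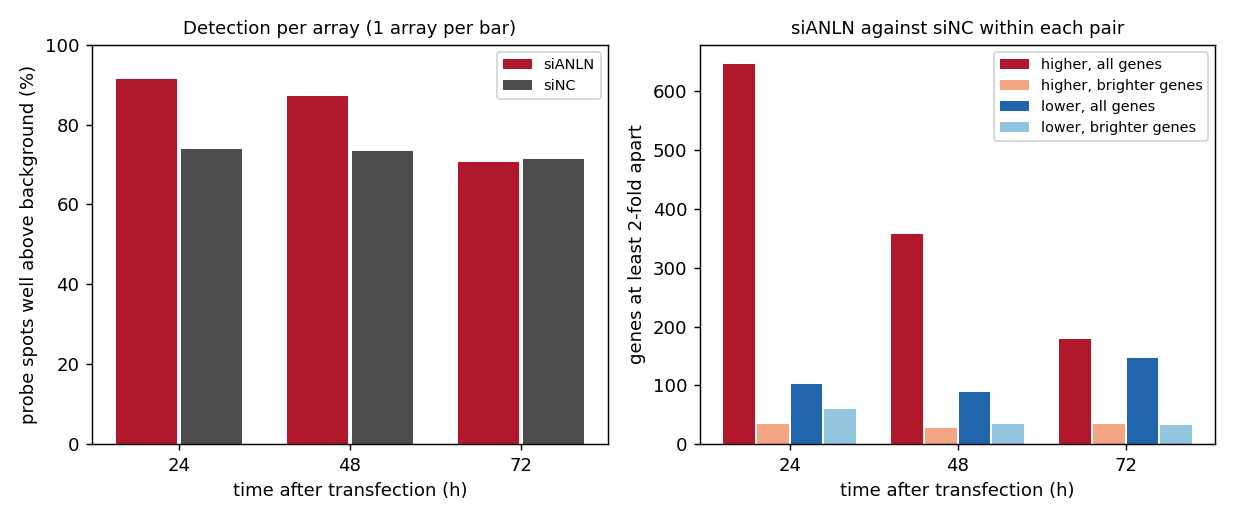
Left, the percentage of probe spots well above background on each of the 6 arrays; right, the number of genes at least 2-fold higher or lower in siANLN at each time point, over all genes tested and over the brighter genes (mean signal above the median). Detection is highest at 91.4% and 87.2% on the siANLN arrays of 24 h and 48 h, and the number of higher genes falls from 647 to 179 over all genes but runs 34, 28 and 35 over the brighter ones.

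No gene differed between 72 h and 24 h at the threshold (0 of 19361 in limma, with 1393 at unadjusted p < 0.05 where 968 are due by chance, lowest adjusted p = 0.189). The genes of smallest p that were at least 2-fold lower at 72 h did not pass. They included TBC1D26 with a log2 change of -1.25 ± 0.07 (SE), the signalling adaptor gene DOK2 with -1.19 ± 0.08, the pseudogene EGFEM1P with -1.09 ± 0.07, the hair keratin gene KRT35 with -1.003 ± 0.07, and the olfactory receptor genes OR8U1 and OR51T1 with -1.13 and -1.01. In the other direction ZP4 met the rule, and no size is given, since it was not well above background on any siNC array. Members of the hypoxia and glycolysis list stood higher at 72 h relative to other genes (median 0.04, camera adjusted p = 0.0026, adjusted p = 0.698 with an estimated correlation), although 0 of its 30 members passed alone. The median over all genes was -0.03, and against no change with time fry gave an adjusted p of 0.971 for this list.

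No gene passed the test for a change of the siRNA effect with time (0 of 19361 in limma, lowest adjusted p = 0.306). At unadjusted p < 0.05 in limma there were 2269, where 968 are due by chance. With 200 genes changed in the simulation, this test recovered 0% of slopes of 0.5 per 24 h and 16.4% of slopes of 1. The count of 0 therefore does not show that the effect was constant. The trends that the naming rule takes, by smallest unadjusted p and not by size, did not pass. The siANLN to siNC log2 ratio of OSMR, a receptor subunit for oncostatin M, went from -0.80 at 24 h to 0.97 at 72 h, a slope of 0.89 ± 0.13 (SE) per 24 h, and that of CCNP went from -1.67 to 0.98. The ratios of SEMA3E, ETV2 and GPA33 had slopes of 0.58, 0.62 and 0.73. ANKRD34B also met the rule, without a size, since it was not well above background on any siNC array. Slopes were negative for PREX2, an exchange factor for Rac (-1.41 ± 0.06), CCDC158 (-1.26), SMIM5 (-1.11), SLITRK6 (-0.97), ODF4 (-0.97) and SH3D21 (-0.91). The SD over the time points was larger in siNC than in siANLN for OSMR (1.07 against 0.22), CCNP (1.69 against 0.54) and ETV2 (0.64 against 0.08). It was larger in siANLN for GPA33 (0.83 against 0.17) and SMIM5 (1.01 against 0.17). The siANLN array of 72 h was scanned apart from those of 24 h and 48 h, so a slope cannot be told apart from the scan. Relative to other genes, the slopes of the G2/M and mitosis list (median 0.02) and of the blood cell markers (-0.24) passed at the preset correlation, with camera adjusted p of 0.0234 and 0.0291, and both had an adjusted p of 0.833 with an estimated correlation. Against no change with time, fry gave adjusted p of 0.972 and 0.267, and 0 members of either list passed alone.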

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

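The tests on dim probes, on the scans and on the interferon list, and fry's test, were chosen only after the results were seen. The fixed lists of G2/M and mitosis genes and of blood cell markers stand out because their slopes with time differed from those of other genes at the preset correlation, though not with an estimated one (adjusted p = 0.833), nor from no change in fry's test (adjusted p of 0.972 and 0.267). The median change of the siANLN to siNC log2 ratio per 24 h was 0.0207 for G2/M and mitosis, against -0.03 for all genes, and -0.24 for the blood cell markers, of which 5 of 15 belong to the brighter genes (mean signal above the median of all genes tested).

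More genes were at least 2-fold higher in siANLN at 24 h and 48 h (647 and 358) than at 72 h (179). Dim probes reading higher on the siANLN arrays of scan 1 may account for the excess, since it was gone in the brighter genes (34 genes at 24 h against 35 at 72 h). Scaling on the 75th percentile may contribute too, since quantile normalization left 235 higher genes at 24 h (and 263 lower) against 158 at 72 h, just within the bound of 1.5 times. A larger effect of the siRNA at 24 h stays open. Among the 2484 called brighter genes the median absolute log2 ratio at 24 h was 0.971 times that at 72 h, which decides nothing, since a call needs the pairs to be alike and the excess lies in dim genes.

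The interferon response list was higher in siANLN. Dim probes are argued against, since 37 of its 39 genes are among the brighter genes and had a median of 0.35. The scan of the siANLN arrays at 24 h and 48 h is argued against too, since the 72 h pair, whose siANLN array was scanned apart, had a median of 0.31 with 30 of 39 genes above 0. Scaling moved the median only between 0.30 and 0.45. The scan of the control arrays stays open and cannot be told apart from the siRNA, since 0 of 3 scans hold both groups. An effect of lower ANLN, and a reaction to this siRNA that does not pass through ANLN, were not tested.

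The G2/M and mitosis list was lower in siANLN. A general reading of bright probes as lower is argued against as the whole cause, since the 5th percentile of lists matched on mean signal was -0.12 and the list stood at -0.25. The scan of the siANLN arrays at 24 h and 48 h is argued against, since the 72 h pair had a median of -0.20 with 41 of 47 genes below 0. The scan of the control arrays cannot be told apart from the siRNA, with 0 of 3 scans holding both groups. A change in the share of dividing cells was not tested.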

How the results depend on the processing

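The restriction to genes with a mean signal above the median was chosen after the data were seen; all other alternatives were fixed beforehand. The count of genes that differed between siANLN and siNC (4758) stayed within 1.5 times, at 3782 to 6842, under several alternatives. These were the 4 other scalings and sources of values, the stricter filter, both treatments of several probes, the fit without the time point, and the intensity trend with a robust prior. Of the 3782 genes called with quantile normalization, 3012 were among the 4758. The restrictions to brighter genes tested only 9680 genes, so their counts cannot be set directly against 4758. There 4371 were called, 1539 higher and 2832 lower, and with quantile normalization 3937, with 1823 higher and 2114 lower. With the scan as a random block and no time point the count over all genes was 7585, which says nothing about a scan effect, since no scan holds both groups. It was 0 without the filter on dim probes, 190 at unadjusted p < 0.05 with at least 2-fold, and 0 to 2679 on leaving out 1 array, where the fit keeps 1 residual degree of freedom and the partner of the missing array no longer adds to the comparison. ANLN kept its direction throughout, with -1.98 and an adjusted p of 0.101 without the filter and -2.05 to -1.90 without 1 array. Genes at least 2-fold apart at all time points (93) numbered 32 with normexp and quantile normalization, 33 among the brighter genes, 30 there with quantile normalization, and 119 to 229 on leaving out 1 array, since 2 time points then remain. The 5 gene lists past the threshold became 0 with an estimated correlation and 4 to 7 in the other alternatives. The loss cannot be laid to correlation alone, since camera then uses only the few residual degrees of freedom. For the contractile ring list the estimated correlation was -0.019, below the preset 0.01, yet its unadjusted camera p rose from 6.0e-05 to 0.0433. The counts of 0 for the time contrast and for the slope stayed at 0 in all alternatives run. All 24 named genes kept their direction in every setting that tested them; the 24 lost their call without the filter and without either array of 24 h or 48 h, and 1 of 24 without either array of 72 h. Apart from the effects of fewer arrays, of leaving the time points out and of testing other genes, the cause was not tested.

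The scan as a block was not run for the time contrast, the slope or the lists, since the correlation could not be estimated with the time point in the fit and camera takes no block. With low signal over background, genes near the detection limit have uncertain sizes.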

Other observations

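The gene families in these first 2 paragraphs, and the genes named from them, were chosen after the data were seen, and all of their camera calls were lost with an estimated correlation (adjusted p of 0.618). Chemokine genes were mostly higher in siANLN. Of 23 tested 12 rose and 2 fell (median 0.42, 0.35 to 0.48 over the other scalings, camera adjusted p = 0.0063 at the preset correlation). CCL3 rose by 1.31 ± 0.08 on the log2 scale (SE, higher in 3 of 3 pairs), CXCL11 by 0.99, CCL4 by 0.87 and CXCL8 by 0.83, while CCL26 fell by 0.77 and CCL2 by 0.52. Zinc finger genes with ZNF names rose in 115 of 424 cases and fell in 26 (median 0.15, 0.07 to 0.08 over the other scalings, camera adjusted p = 0.0040), with a median of 0.07 in lists matched on mean signal. Olfactory receptor genes rose in 22 of 104 cases and fell in 1 (median 0.28, 0.07 to 0.22 over the other scalings, camera adjusted p = 9.0e-05). Their matched lists had a median of 0.19, so dim genes in general read higher in siANLN, and the observed median stood at the 99.9th percentile. The family's median was 0.355 at 24 h and 0.346 at 48 h, whose siANLN arrays formed scan 1, but 0.116 at 72 h. The matched lists were compared over the 3 pairs together. The percentile therefore cannot tell a change of this family from dim probes reading higher in scan 1.

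Of 77 mitochondrial ribosome genes 26 fell in siANLN and 0 rose (median -0.18, camera adjusted p = 2.2e-09), led by MRPS10 at -0.73 ± 0.05 and MRPL50 at -0.70 ± 0.05 (SE). Of 36 complex I subunit genes 11 fell and 1 rose (median -0.22, camera adjusted p = 9.1e-07). Bright genes read lower in siANLN in general, and lists matched on mean signal had medians of -0.09 and -0.13; the observed medians stood at the 0.04th and 0.47th percentile. Over the other scalings the medians ran from -0.25 to -0.08 and from -0.29 to -0.08. Of 85 cytosolic ribosomal protein genes 16 fell and 0 rose, with a median of -0.30, which ran from -0.37 to -0.04 over the other scalings. Their matched lists had a median of -0.27 and a 5th percentile of -0.29, and the observed median stood at the 1.35th percentile.

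Among the 10 ways to split the 6 arrays into groups of 3, the real split called 4758 genes and the highest other 1, and it alone reached its count (1 of 10). For the lists, the real split put 5 past the threshold and the highest other 5, with 4 of 10 splits reaching that number. The count for genes was known before its test was set; that for lists was not. With 10 splits no share under 0.05 can be had. The time point pairs the arrays, and the other 3 splits that part all 3 pairs called 0 genes. The remaining splits part only 1 pair, so their comparison rests on that pair. Every other split leaves differences between siANLN and siNC in the residual, so low counts there were largely fixed in advance. The real split also parts scan 3 from scans 1 and 2, so its count cannot tell the siRNA from the scan. From the 24 h and 48 h pairs alone, 80.7% of the 1000 genes of smallest p had the same sign in the 72 h pair, against 75.1% of all genes.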
